A study of Homo sapiens with 9 samples.

How the data were processed

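Total RNA of BT-20 cells, an established human breast carcinoma line, was measured on 9 Affymetrix oligonucleotide arrays. Per the labels, 3 arrays held RNA of mock-transfected cells, 3 of cells transfected with a small interfering RNA (siRNA) against green fluorescent protein (GFP), a gene that human cells do not carry, and 3 of cells transfected with an siRNA against FoxM1. The labels number the replicates of each group 1 to 3. They do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The siRNA sequences, the time after transfection and the RNA preparation were not given in the sources used here.

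The deposited table holds 1 intensity per probe set and array, in whole numbers from 1 to 1276. Its unit, scaling target and software were not given in the sources used here, and no detection calls were used. The values were taken as linear and already scaled, because the mean of each array without its highest and lowest 2% lay between 17.96 and 17.99. The median of each array was 5 or 6. Because the highest and lowest medians differed 1.2-fold, under the limit of 1.25 set beforehand, the deposited values were used without further normalization. Medians of 5 and 6 are 1 rounding step apart, so this check could not see a finer difference in scale. Scaling to equal medians, an alternative below, shifts mock replicate 3 and FoxM1 siRNA replicate 3, with medians of 6, by that step. Calls that it ended may therefore reflect rounding. An array has no read depth, so the number of arrays limits the precision. Rounding to whole numbers adds a coarse step to dim probe sets. Of all tested probe sets, 37.3% had a mean under 10.

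The table held 22283 probe sets. Of these, 68 were control probe sets (AFFX) and were left out of the comparisons. Values under 2, the 20th percentile of all values, were set to 2, and log2 was taken. Probe sets were tested if their mean over the 9 arrays was above 3.33, the 40th percentile of such means, which left 13214. Among the tested values, 1.25% lay at or below the floor. In the platform annotation, 19065 probe sets had 1 gene symbol, 1043 had several and 2107 had none. Among those tested the numbers were 11729, 643 and 842. The Entrez identifiers of 19053 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCh38.p14, used for names only, and no symbol changed. No gene was named from a probe set with several symbols, and no genome position is given because the table names no build. Where a gene had several probe sets, the one with the highest mean over the 9 arrays stood for it, which gave 8042 genes.

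The 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit with a mean for each of the 3 groups, then eBayes with a mean-variance trend). Contrasts compared FoxM1 siRNA with GFP siRNA, FoxM1 siRNA with mock, GFP siRNA with mock, and FoxM1 siRNA with the average of both controls. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The difference between the 2 siRNAs, each set against mock, equals the first contrast and was not tested separately. Group values are means of deposited intensities ± SD over 3 arrays, and fold changes are those fitted on the log2 scale with their standard error (SE).

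A set of 23 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, with adjustment over the lists within a comparison. Camera with an estimated correlation and limma's fry were run beside it. Each list past camera's threshold also passed with fry (fry adjusted p from 0.0035 to 0.0424), while none passed with an estimated correlation. Against GFP siRNA, fry alone also passed the lists of cholesterol and lipid synthesis and of extracellular matrix, proteases and invasion (fry adjusted p = 0.0478 each). Counts of list members were also taken with the p-values adjusted over the list alone. Over the 69 pairs of list and comparison, the sign of the median, the mean and the test differed in 11, none of them past the threshold. The sample groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took FOXM1, then for each of the first 3 comparisons the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 arrays in one group lay above all 3 in the other. To these it added, from each list, up to 4 members past the threshold with the smallest adjusted p. Complete separation of 3 arrays from 3 has a 10% chance without any effect.

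The scripts were tested on simulated data in which 50 probe sets at each of 4 fold sizes were changed in FoxM1 siRNA. In the comparison with GFP siRNA, over 13214 probe sets, limma recovered 40% of the 1.5-fold changes, 76% of the 2-fold, 94% of the 3-fold and 96% of the 4-fold, with 8 false calls among 161. In the simulated comparison of GFP siRNA with mock, where nothing was changed, it called 0. A list shifted by 0.3 on the log2 scale was called, and 0 of 22 other lists were. The simulated noise was independent between probe sets, so this does not show how often lists of correlated genes are called falsely. On the real arrays, a regrouping of the GFP siRNA and mock arrays gave as many as 6 lists.

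Alternatives were quantile normalization, scaling to equal medians, other floors, an offset in place of the floor, no filter or a stricter one, the replicate number as a block, eBayes without the trend or robust, array weights, a fit of only the compared groups, 1 probe set per gene, stricter thresholds, and leaving out each array in turn. Scaling to equal mean log2 values and a filter at a mean of 20 were added after the data were seen. No 2 arrays held identical values, and pairs of arrays correlated between 0.965 and 0.980 over the tested probe sets. The median correlation with the own group was 0.971, 0.972 and 0.972 for mock replicates 1, 2 and 3. With the other groups it was 0.971, 0.972 and 0.975. For GFP siRNA and FoxM1 siRNA arrays it was 0.978 to 0.980 with the own group and 0.972 to 0.975 with the others. The mock arrays were thus not clearly closer to each other than to the other groups.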

Results

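Gene expression was measured in BT-20 human breast carcinoma cells after transfection with an siRNA against FoxM1, a forkhead transcription factor whose messenger RNA is abundant in dividing cells. Each of the 3 groups (mock transfection, GFP siRNA and FoxM1 siRNA) had 3 arrays, and 13214 probe sets for 8042 named genes were tested. The series title gives the profile of cells treated with FoxM1 siRNA as its subject. The control siRNA and the mock transfection each served as a baseline, and their comparison with each other measured the difference made by a control siRNA.

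FOXM1 itself was low on all 3 arrays of the targeted group. Its single probe set read 76.3 ± 9.07 after mock transfection, 71.7 ± 7.02 after GFP siRNA and 13 ± 1 after FoxM1 siRNA (mean intensity ± SD, n = 3 arrays each). It fell 5.51-fold against GFP siRNA (log2 fold change −2.46, SE 0.11, limma adjusted p = 1.59e-07) and 5.86-fold against mock (−2.55, adjusted p = 1.01e-07). The single arrays read 12, 13 and 14 after FoxM1 siRNA and 65 to 86 in the 6 control arrays. Between GFP siRNA and mock the log2 difference was −0.09 (adjusted p = 0.853).

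**Figure D1:**
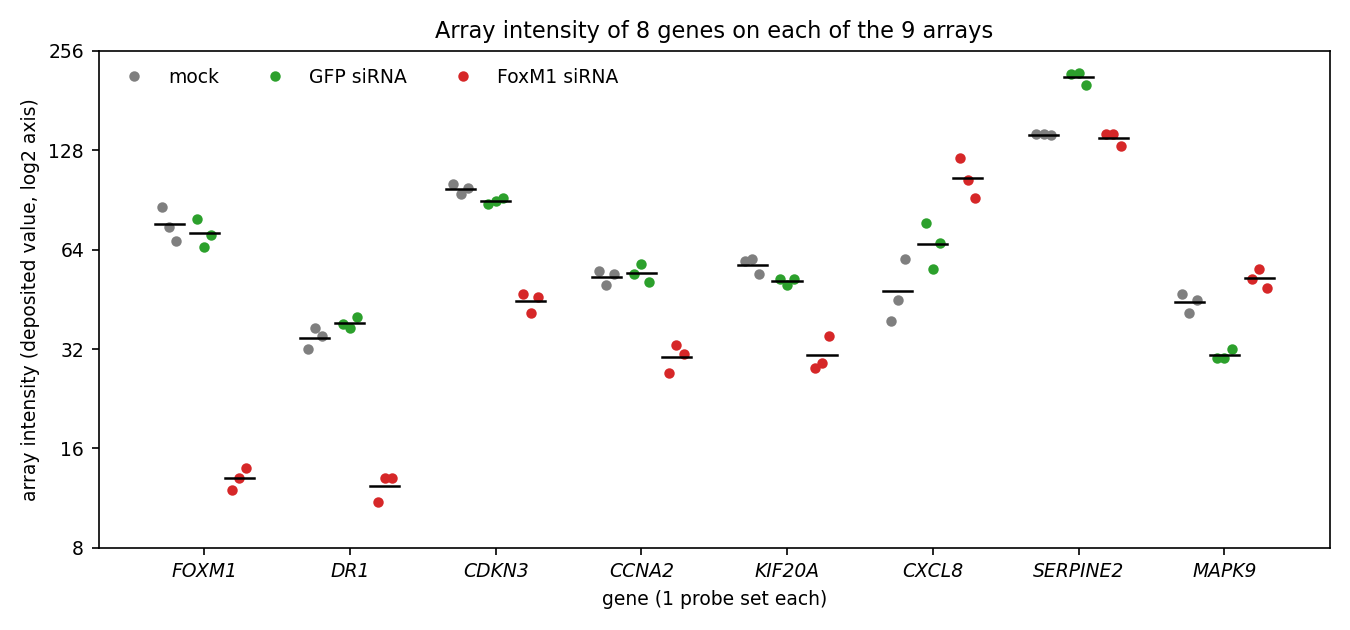
Deposited array intensity (log2 axis) of 8 genes on the 9 arrays; each point is 1 array, grey for mock, green for GFP siRNA and red for FoxM1 siRNA, and each bar is the mean of 3. FOXM1, DR1, CDKN3, CCNA2 and KIF20A are lowest on the FoxM1 siRNA arrays, while SERPINE2 and MAPK9 set the GFP siRNA arrays apart from both other groups.

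Against GFP siRNA, several genes of late cell cycle and mitosis fell in cells that received FoxM1 siRNA. CDKN3, a phosphatase that acts on cyclin-dependent kinases, fell from 90 ± 2 to 44.7 ± 3.21 (log2 fold change −1.01, SE 0.08, adjusted p = 5.21e-05). CDC25B, a phosphatase that activates these kinases, fell 1.90-fold (−0.93, SE 0.14, adjusted p = 0.00607), and cyclin A2 (CCNA2) fell 1.79-fold (−0.84, SE 0.10, adjusted p = 0.00135). The cytokinesis kinesin KIF20A fell 1.68-fold (adjusted p = 0.00293), securin (PTTG1) 1.55-fold (adjusted p = 0.00575), the centromeric histone CENPA 1.55-fold (adjusted p = 0.0425) and the centrosomal kinase NEK2 1.54-fold (adjusted p = 0.0280). The spindle pole protein ASPM and the abscission protein CEP55 fell 1.38-fold and 1.35-fold (adjusted p = 0.0169 and 0.0268). With 1 array left out, CDKN3, CCNA2 and KIF20A passed in all 9 fits. CDC25B missed the threshold without GFP siRNA replicate 3 (adjusted p = 0.0506) and PTTG1 without FoxM1 siRNA replicate 3 (0.0556). CENPA, NEK2, ASPM and CEP55 passed in 2, 3, 4 and 3 of the 9 fits, with highest adjusted p of 0.207, 0.128, 0.0915 and 0.132. Scaling to equal medians ended the calls of CEP55 (0.156), ASPM (0.0831) and CENPA (0.0509), and the fit without the filter those of NEK2 (0.161), CDC25B (0.0935) and PTTG1 (adjusted p = 0.0590).

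As a list, G2/M cyclins and kinases were lower than other genes (camera adjusted p = 0.0211), with 3 of 20 tested members falling (CDC25B, CCNA2 and NEK2), 0 rising and 17 not passing; adjusted over the list alone, 4 fell. The call was lost with an estimated correlation (adjusted p = 0.148), with quantile normalization (0.0674), with the filter at the 60th percentile (0.0785), without GFP siRNA replicate 1 (0.0948) and without FoxM1 siRNA replicate 1 (0.0669). Other cell cycle lists did not pass. Of 27 spindle and cytokinesis genes 3 fell (KIF20A, ASPM and CEP55) and 0 rose (adjusted p = 0.277); adjusted over the list alone, 4 fell and 1 rose. Of 27 kinetochore and spindle checkpoint genes 1 fell, CENPA (0.543), and adjusted over the list alone 1 fell and 2 rose. Of 15 mitotic exit and anaphase-promoting complex genes 1 fell, PTTG1 (0.543), also when adjusted over the list alone. None of 19 condensin, cohesin and topoisomerase genes (0.374), 24 centrosome and centriole genes (0.543), 47 DNA replication and G1/S genes (0.277) and 21 homologous recombination genes (0.926) passed limma's test, nor when adjusted over the list alone.

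Outside the cell cycle, DR1, a repressor that binds the TATA-binding protein, had the largest fall after FOXM1 among genes read from their brightest probe set. It went from 38.3 ± 1.53 after GFP siRNA to 12.3 ± 1.15 after FoxM1 siRNA (log2 fold change −1.64, SE 0.11, adjusted p = 4.76e-06). The 3 other tested DR1 probe sets fell by 1.74, 1.75 and 1.95 on the log2 scale, and a further DR1 probe set read 1 or 2 on every array and was not tested. A dim probe set of TSC22D3, noted after its values were seen, fell by 1.90 (adjusted p = 0.00826), while the brighter TSC22D3 probe set did not pass (log2 difference −0.41, adjusted p = 0.0599). QTMAN, a glycosyltransferase that modifies queuosine in transfer RNA, fell 2.74-fold (adjusted p = 0.000115) on 1 probe set. Its dimmer probe set gave a log2 difference of 0.14 (adjusted p = 0.870). The zinc finger gene ZNF302 fell 2.13-fold (adjusted p = 0.00567), MMD 2.07-fold (adjusted p = 0.0111), the receptor phosphatase PTPRG 2.06-fold (adjusted p = 0.0127) and the glucosamine-6-phosphate deaminase GNPDA1 1.95-fold (adjusted p = 0.00381). DR1, QTMAN, ZNF302 and GNPDA1 passed with each array left out in turn, and MMD and PTPRG passed in 5 and 4 of these 9 fits (highest adjusted p 0.0613 without GFP siRNA replicate 1 and 0.0819 without FoxM1 siRNA replicate 3). Without the filter the calls of PTPRG (0.127), MMD (0.0826) and GNPDA1 (0.0585) were lost.

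Histone genes were lower after FoxM1 siRNA than after GFP siRNA (camera adjusted p = 1.82e-06; adjusted p = 0.147 with an estimated correlation, which ended the call). Of 11 tested members 3 fell, 0 rose and 8 did not pass; adjusted over the list alone, 5 fell. H2AC6 fell 1.94-fold (adjusted p = 0.0169), the linker histone H1-2 1.56-fold (adjusted p = 0.0137) and H2BC12 1.46-fold (adjusted p = 0.0169). For H2AC6 and H1-2 the FoxM1 siRNA level was near that of mock. H1-2 read 20.7 ± 1.53 after mock transfection, 38.7 ± 4.51 after GFP siRNA and 24.7 ± 1.15 after FoxM1 siRNA. Each of the 3 genes passed in 5 of the 9 fits with an array left out, with highest adjusted p of 0.114, 0.0912 and 0.115 without FoxM1 siRNA replicate 3. Genes of endoplasmic reticulum and amino acid stress were also lower as a list (camera adjusted p = 0.0142; 0.148 with an estimated correlation, 0.0674 with quantile normalization, 0.0617 with the filter at the 60th percentile). Of 24 members 2 fell, both also when adjusted over the list alone. The cystine transporter SLC7A11 fell 1.49-fold (adjusted p = 0.0119) and HERPUD1, a component of protein degradation at the endoplasmic reticulum, 1.32-fold (adjusted p = 0.0370); SLC7A11 read 65.3 ± 7.09 after mock transfection and 66.0 ± 2.65 after FoxM1 siRNA. With an array left out, SLC7A11 passed in 4 and HERPUD1 in 2 of 9 fits. Without the filter the calls of H2AC6 (0.125), H2BC12 (0.0985) and SLC7A11 (0.0723) were lost, H1-2 was lost without the variance trend (0.0691), and HERPUD1 with scaling to equal medians (0.175).

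Against GFP siRNA the largest rises among named genes, each read from its brightest probe set, were those of LEMD3, SERINC1 and INHBA. LEMD3, an inner nuclear membrane protein, rose 1.95-fold (adjusted p = 0.0346) and SERINC1 1.89-fold (adjusted p = 0.00254). INHBA, which encodes a subunit of activin, rose 1.89-fold (adjusted p = 0.00135). A dimmer INHBA probe set read 3, 5 and 3 after GFP siRNA and 11, 9 and 7 after FoxM1 siRNA. CDH5 (1.84-fold, adjusted p = 0.00295), an endothelial cadherin on the list of stromal and immune cell markers, rose from 13.7 ± 1.53 to 25 ± 1 and read 20.7 ± 1.53 after mock transfection. MAPK9, a stress-activated kinase, rose 1.70-fold (adjusted p = 0.00151) and COX11, an assembly factor of cytochrome oxidase, 1.66-fold (adjusted p = 0.0169). The kinase NEK4, the vesicle tethering subunit TRAPPC4, the kinase NUAK1 and the CTP synthase CTPS1 rose 1.55-fold, 1.55-fold, 1.55-fold and 1.54-fold (adjusted p from 0.00991 to 0.0346). For each of these 10 genes the mock mean lay above the GFP siRNA mean, and none passed the threshold for FoxM1 siRNA against mock (adjusted p from 0.0542 for INHBA to 0.917 for COX11). All 3 FoxM1 siRNA arrays still lay above all 3 mock arrays for INHBA, CTPS1, NUAK1, MAPK9, CDH5 and SERINC1. SERINC1, INHBA, CDH5 and MAPK9 passed with each array left out in turn. NUAK1 passed in 6 of 9 such fits, COX11 and TRAPPC4 in 5, CTPS1 in 4, NEK4 in 2 and LEMD3 in 0 (highest adjusted p 0.189, without FoxM1 siRNA replicate 3). Scaling to equal medians ended the calls of NEK4 (0.209), CTPS1 (0.171), NUAK1 (0.138), TRAPPC4 (0.136) and COX11 (0.0679), and the fit without the filter those of LEMD3 (0.229) and SERINC1 (0.0590).

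Genes of the NF-kB and inflammatory cytokine list were higher after FoxM1 siRNA than after GFP siRNA (camera adjusted p = 0.00223; 0.201 with an estimated correlation). Of 17 tested members 1 rose, the adhesion molecule ICAM1 (1.51-fold, adjusted p = 0.0438), and adjusted over the list alone 4 rose. ICAM1 passed in 1 of 9 fits with an array left out, and its adjusted p reached 0.192 without FoxM1 siRNA replicate 3. Among 21 genes of extracellular matrix, proteases and invasion the urokinase receptor PLAUR rose 1.46-fold (adjusted p = 0.0346) and the protease inhibitor SERPINE2 fell 1.53-fold (adjusted p = 0.00155), and the list did not pass (0.277; the same 1 and 1 adjusted over the list alone). TP53I3, a quinone oxidoreductase induced by p53, fell 1.38-fold (adjusted p = 0.0201) and was the only 1 of 21 CDK inhibitors and p53 targets past the threshold (list 0.297), also when adjusted over the list alone. For SERPINE2 and TP53I3 the GFP siRNA arrays stood apart, with means of 143, 213 and 139 and of 44, 59 and 42.7 in mock, GFP siRNA and FoxM1 siRNA (adjusted p = 0.895 and 0.888 for FoxM1 siRNA against mock). SERPINE2 passed in all 9 fits with an array left out, TP53I3 in 3 (highest adjusted p 0.101, without GFP siRNA replicate 2) and PLAUR in 2. Scaling to equal medians ended the calls of PLAUR (0.311), ICAM1 (0.270) and TP53I3 (0.108). CDH5 was the only 1 of 9 tested stromal and immune markers past it (list 0.220), also when adjusted over the list alone. No member passed among 24 apoptosis regulators (0.277), 34 interferon response genes (0.543), 15 heat shock proteins (0.149), 19 cholesterol and lipid synthesis genes (0.277), 21 keratins and breast epithelial markers (0.543), 10 forkhead genes (0.277), 9 genes of small RNA machinery (0.926), 25 immediate early genes (0.277) and 14 reference genes (0.583). Adjusted over the list alone, 3 apoptosis regulators fell, 1 forkhead gene and 1 immediate early gene rose, and 0 members of the other 6 lists passed.

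**Figure D2:**
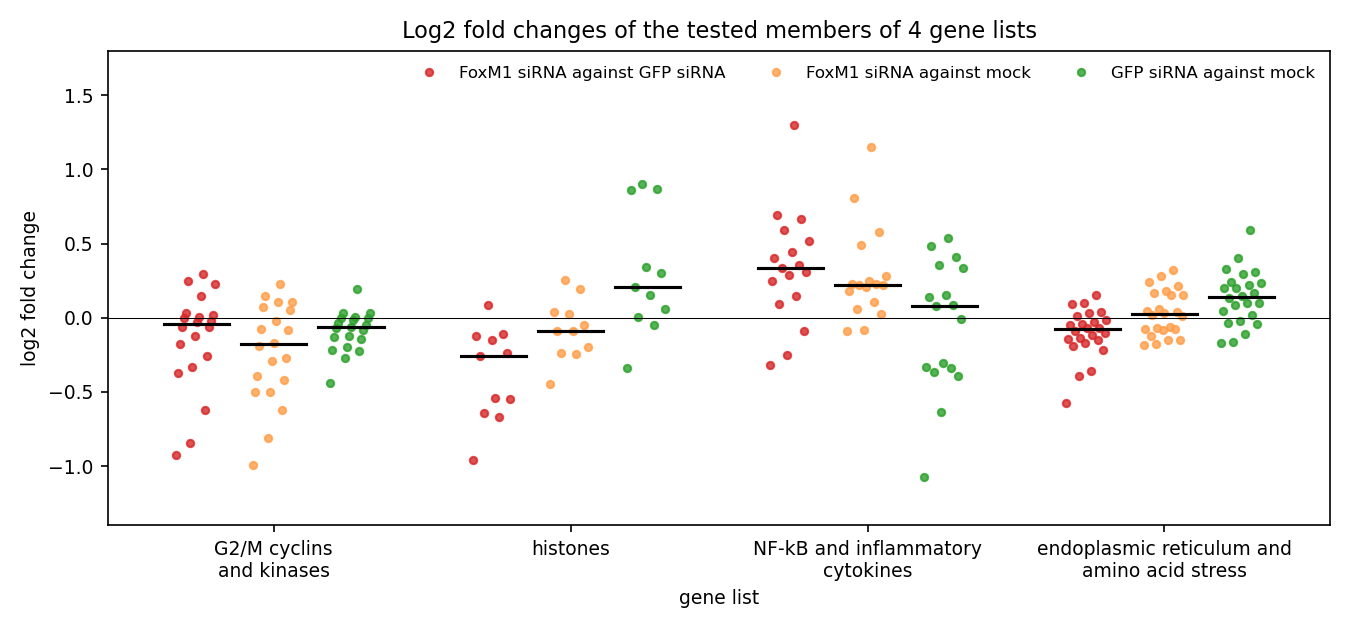
Log2 fold changes of the tested members of 4 gene lists (20, 11, 17 and 24 genes) in each of 3 comparisons; each point is 1 gene and each bar the list's median. The histone median was −0.26 for FoxM1 siRNA against GFP siRNA, −0.09 against mock and 0.21 for GFP siRNA against mock, and the NF-kB median was 0.33 and 0.22 against the 2 controls.

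In total, 48 probe sets (37 named genes) were higher and 92 (74 named genes) lower after FoxM1 siRNA than after GFP siRNA, out of 13214; at an unadjusted p under 0.05 the counts were 920 and 848. The median fold change of those past the threshold was 1.54 for rises and 1.55 for falls. The higher probe sets were 34.3% of the calls, against 18.2% of the calls with scaling to equal medians and 25.2% with scaling to equal mean log2 values. The medians are whole numbers, so part of the change with equal medians may reflect rounding. Equal mean log2 values do not depend on that step and moved the share the same way, so the share depended on the scaling. The total of 140 was 44, 56 and 72 without FoxM1 siRNA replicates 3, 2 and 1, and 49, 65 and 64 without GFP siRNA replicates 3, 2 and 1.

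Against mock transfection, CDKN3 and other cell cycle genes fell, CENPE rose, and some genes of inflammation and growth factor signalling rose. ASPM, which fell against GFP siRNA, did not pass against mock (log2 fold change −0.16, adjusted p = 0.430). CDKN3 fell 2.19-fold (log2 fold change −1.13, SE 0.08, adjusted p = 1.38e-05), CDC25B 1.99-fold (adjusted p = 0.00474), KIF20A 1.89-fold (adjusted p = 0.000709), and CENPA 1.88-fold (adjusted p = 0.00600). CCNA2 fell 1.75-fold (adjusted p = 0.00197), PTTG1 1.58-fold (adjusted p = 0.00480), NEK2 1.54-fold (adjusted p = 0.0327), CEP55 fell by 0.59 on the log2 scale (adjusted p = 0.00567) and cyclin B1 (CCNB1) fell 1.34-fold (adjusted p = 0.0306). The kinetochore motor CENPE rose 1.61-fold (adjusted p = 0.0422). With an array left out, CENPA missed the threshold without FoxM1 siRNA replicate 3 (adjusted p = 0.0509). NEK2, CCNB1 and CENPE passed in 1, 2 and 1 of 9 fits (highest adjusted p 0.143, 0.130 and 0.155), and the others passed in all 9. Scaling to equal medians ended the calls of CCNB1 (0.293), CEP55 (0.0849) and NEK2 (0.0628), and the fit without the filter those of CENPE (0.129), CENPA (0.0979), CDC25B (0.0942) and PTTG1 (0.0604). The G2/M list was lower (camera adjusted p = 0.000198, 0.0652 with an estimated correlation), with 4 of 20 members falling, and 8 falling and 1 rising when adjusted over the list alone. Spindle and cytokinesis genes were lower (adjusted p = 0.00200, 0.0704 with an estimated correlation; 2 of 27 fell, and 5 fell and 1 rose adjusted over the list alone). DNA replication and G1/S genes were lower too (0.00306, 0.0903 with an estimated correlation, 0.130 without mock replicate 3), although 0 of 47 members passed and 2 fell when adjusted over the list alone. The median log2 fold change of these genes was −0.07 against mock, but also −0.09 for GFP siRNA against mock, and −0.03 for FoxM1 siRNA against GFP siRNA. For spindle and cytokinesis genes the medians were −0.14, −0.13 and 0.01 in the same order of comparisons, and the means −0.14, −0.10 and −0.04. Much of the lower level of both lists against mock was therefore also present after GFP siRNA.

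The chemokine CXCL8 had the largest rise against mock among the named genes, from 48.0 ± 10.8 to 106 ± 14.6 (log2 fold change 1.15, SE 0.16, adjusted p = 0.00459), and GFP siRNA arrays read 66.7 ± 10.5 (log2 difference of FoxM1 siRNA from GFP siRNA 0.67, adjusted p = 0.0678). CXCL2 rose 1.75-fold (adjusted p = 0.0306). With these 2 of 17 members rising, 2 also when adjusted over the list alone, the NF-kB and inflammatory cytokine list was higher (camera adjusted p = 0.00302, 0.192 with an estimated correlation, 0.0801 without mock replicate 3). The growth factor EREG rose 1.88-fold (adjusted p = 0.0372), the only 1 of 25 immediate early and growth factor response genes past the threshold, 2 when adjusted over the list alone. That list was higher (0.0254), and its call was lost with an estimated correlation (adjusted p = 0.181), with the mean of each gene's probe sets (0.565), with the filter at the 60th percentile (0.0972), without mock replicate 3 (0.175) and without FoxM1 siRNA replicate 3 (0.0934). The scaffold protein AKAP12 rose 1.87-fold (adjusted p = 0.00192), the folate receptor FOLR1 1.76-fold (adjusted p = 0.0406), S100A2 1.66-fold (adjusted p = 0.0170), and DOCK9 1.63-fold (adjusted p = 0.0476). A rise was also seen for the steroid dehydrogenase HSD3B1 (1.59-fold, adjusted p = 0.00704), the zinc finger gene MAZ (1.59-fold, adjusted p = 0.00600) and the laminin chain LAMB3 (1.33-fold, adjusted p = 0.0254). MAZ had another probe set with the opposite sign. A dimmer FOLR1 probe set read 5, 4 and 8 after mock transfection and 7, 6 and 5 after FoxM1 siRNA. Most of the rise of MAZ, DOCK9 and LAMB3 was also present after GFP siRNA, with log2 differences of 0.11, 0.15 and 0.15 between the 2 siRNAs (adjusted p = 0.675, 0.720 and 0.415). CXCL2 was intermediate after GFP siRNA, 0.41 above mock (limma adjusted p = 0.411) and 0.40 below FoxM1 siRNA (0.281) on the log2 scale. CXCL8, AKAP12 and MAZ passed with each array left out, HSD3B1 missed it without FoxM1 siRNA replicate 3 (0.0509). S100A2, LAMB3, CXCL2, FOLR1, EREG and DOCK9 passed in 5, 3, 2, 2, 1 and 0 of 9 fits. Without the filter CXCL8 missed the threshold (adjusted p = 0.117), as it did without the variance trend (0.0573) and in the fit of the 2 groups alone (0.0506). Scaling to equal medians ended the calls of LAMB3 (0.301), DOCK9 (0.142), CXCL2 (0.0671), S100A2 (0.0596) and MAZ (0.0518). The fit without the filter ended those of FOLR1 (0.229) and EREG (0.219), and the fit of the 2 groups alone that of HSD3B1 (0.0511).

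Against mock the falls of DR1 (2.81-fold, adjusted p = 1.38e-05), QTMAN (2.42-fold, adjusted p = 0.000595), ZNF302 (2.07-fold, adjusted p = 0.00745), PTPRG (1.99-fold, adjusted p = 0.0204) and GNPDA1 (1.95-fold, adjusted p = 0.00474) were of similar size to those against GFP siRNA. The kinase MAPK3 fell 2.73-fold (adjusted p = 0.0306), from 8 ± 1.73 to 3 ± 1. The neuropeptide NMU fell 2.62-fold (adjusted p = 0.0306), from 5.33 ± 1.15 to 2 on each FoxM1 siRNA array, which is the floor. With the floor at the 40th percentile its log2 fold change was −0.81 and the call was lost (adjusted p = 0.125). With an array left out, PTPRG, MAPK3 and NMU passed in 5, 2 and 1 of 9 fits. Without the filter the calls of PTPRG (0.167), MAPK3 (0.164), GNPDA1 (0.0673) and ZNF302 (0.0660) were lost. In total 48 probe sets (42 named genes) were higher and 77 (59) lower than in mock, and at an unadjusted p under 0.05 801 were higher and 966 lower. The total of 125 lay between 41 (without FoxM1 siRNA replicate 3) and 91 (without GFP siRNA replicate 2). It was 68, 72 and 84 without mock replicates 1, 2 and 3, 43 and 51 without FoxM1 siRNA replicates 2 and 1, and 68 and 69 without GFP siRNA replicates 1 and 3. The higher share of 38.4% was 24.3% with scaling to equal medians.

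Other lists did not pass against mock. CENPE rose and CENPA fell among 27 kinetochore and spindle checkpoint genes (camera adjusted p = 0.638; 1 rose and 2 fell adjusted over the list alone), PTTG1 fell among 15 mitotic exit and anaphase-promoting complex genes (0.793; 1 rose and 1 fell adjusted over the list alone), and LAMB3 rose among 21 genes of extracellular matrix, proteases and invasion (0.436; 3 rose adjusted over the list alone). No member passed among histones (0.436; 1 fell adjusted over the list alone), condensin, cohesin and topoisomerase genes (0.638; 1 rose adjusted over the list alone), centrosome and centriole genes (0.915), homologous recombination genes (0.618), CDK inhibitors and p53 targets (0.436) and apoptosis regulators (0.640). The same held for interferon response genes (0.640), endoplasmic reticulum and amino acid stress genes (0.773), heat shock proteins (0.677), cholesterol and lipid synthesis genes (0.599), keratins and breast epithelial markers (0.391), forkhead genes (0.677), small RNA machinery (0.985), stromal and immune markers (0.985) and reference genes (0.915). In these lists, apart from those with a value given, 0 members passed when adjusted over the list alone.

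Genes changed against both controls included FOXM1, DR1, QTMAN, CDKN3, ZNF302, PTPRG, GNPDA1, CDC25B, KIF20A, CCNA2, PTTG1, CENPA, NEK2 and CEP55 on the lower side and AKAP12, S100A2 and HSD3B1 on the higher side. The dimmer CXCL8 probe set was also higher against both (0.58, adjusted p = 0.0425, and 1.14, adjusted p = 0.000709), unlike the brighter one. A probe set of SPTBN1, outside the named genes, rose by 0.96 against GFP siRNA (limma adjusted p = 0.0169) and 1.13 against mock (0.00765). Among probe sets higher against both, it lay furthest above the average of the controls (log2 fold change 1.05). Against both controls in the same direction, 39 probe sets (29 named genes) were lower and 11 (9 named genes) higher, and 0 changed in opposite directions. This total of 50 was 32, 24 and 20 without FoxM1 siRNA replicates 1, 2 and 3, 28, 27 and 24 without GFP siRNA replicates 1, 2 and 3, and 39 without any 1 mock array. Lists of these sizes drawn independently would share 0.536 lower and 0.174 higher, and simulated unchanged groups that shared the FoxM1 siRNA arrays gave 0.02 on average. With nothing changed few probe sets are called at all, so this 0.02 does not measure how much the shared arrays add to the overlap. Among 100 splits of the 9 arrays into 3 groups, the highest count apart from the real grouping was 32. Across probe sets, which are not independent replicates, the log2 fold changes against the 2 controls correlated with r = 0.583 (0.502 simulated) and a covariance of 0.0426 (0.02 simulated). Part of the overlap may come from the shared arrays, since 3 arrays cannot be split into 2 sets of at least 2. Of the 48 probe sets higher than in GFP siRNA 11 were also higher than in mock, and of the 92 lower ones 39 were also lower. For 24 of the 48 and 23 of the 92, GFP siRNA differed from mock more than FoxM1 siRNA did, and 14 of the 140 were also called for GFP siRNA against mock, all in the opposite direction. Against the average of both controls 57 probe sets (47 named genes) were higher and 113 (89) lower, and the higher share of 33.5% was 16% with scaling to equal medians. This total of 170 was 64, 57 and 44 without FoxM1 siRNA replicates 1, 2 and 3, 111 and 96 without GFP siRNA replicates 2 and 3.

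**Figure D3:**
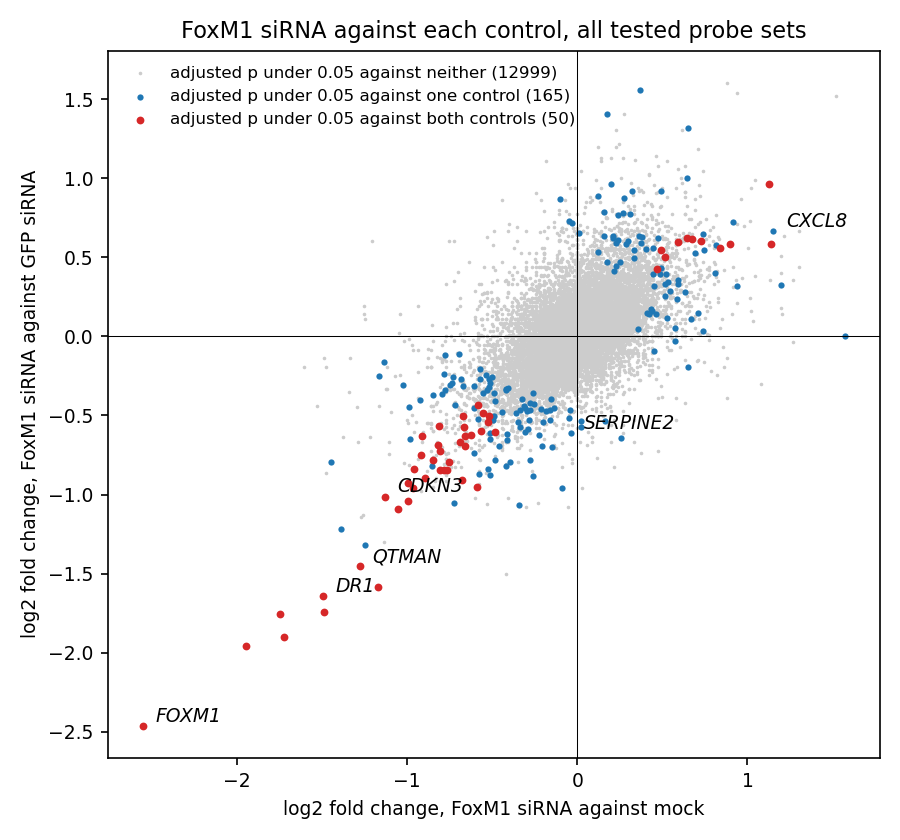
Log2 fold change of FoxM1 siRNA against mock (horizontal) and against GFP siRNA (vertical) for 13214 probe sets; red points passed the threshold against both controls (50), blue points against 1 of them and grey points against neither. FOXM1 (−2.55 and −2.46) lies at the lower left with the DR1 probe sets next to it, and SERPINE2 (−0.04 and −0.61) lies apart from the diagonal.

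The control siRNA by itself changed few genes against mock. Its largest rise past the threshold was 2.97-fold, on a probe set outside the named genes. For FoxM1 siRNA against mock the largest rise was also 2.97-fold and outside the named genes. Whether both were the same probe set is not given here. H1-2 rose 1.87-fold (log2 fold change 0.90, SE 0.11, adjusted p = 0.0113), the heme oxygenase HMOX1 1.79-fold (adjusted p = 0.0293), SLC7A11 1.51-fold (adjusted p = 0.0329) and SERPINE2 1.49-fold (adjusted p = 0.0113), from 143 ± 0.577 to 213 ± 9.54. MAZ, GOLGB1, H2BC12L and ANXA1 rose between 1.40-fold and 1.47-fold (adjusted p from 0.0329 to 0.0498). COX11 fell 1.71-fold (adjusted p = 0.0417), the antiproliferative gene BTG3 1.63-fold (adjusted p = 0.0310), MAPK9 1.44-fold (adjusted p = 0.0463) and the chaperone HSP90B1 1.38-fold (adjusted p = 0.0440). GOLGB1 and HSP90B1 each had another probe set with the opposite sign. Histones (camera adjusted p = 0.000259, 0.177 with an estimated correlation) and endoplasmic reticulum and amino acid stress genes (0.000492, 0.0905 with an estimated correlation) were higher, with 1 of 11 and 1 of 24 members rising; adjusted over the list alone, 4 histones rose and 1 fell, and 1 stress gene rose. Spindle and cytokinesis genes were lower (0.0495) with 0 of 27 members past the threshold. That call was lost with an estimated correlation (adjusted p = 0.185), with scaling to equal medians (0.312) and in 6 of the 9 fits with an array left out (up to 0.178, without GFP siRNA replicate 3).

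The remaining lists did not pass for GFP siRNA against mock. SERPINE2 rose among 21 genes of extracellular matrix, proteases and invasion (camera adjusted p = 0.932; 2 rose adjusted over the list alone). No member passed limma's test among DNA replication and G1/S genes (0.0821), stromal and immune markers (0.0761; 2 fell adjusted over the list alone), kinetochore and spindle checkpoint genes (0.141), G2/M cyclins and kinases (0.188), heat shock proteins (0.280) and immediate early genes (0.310; 1 rose adjusted over the list alone). The same held for homologous recombination genes (0.441), forkhead genes (0.532), apoptosis regulators (0.555), keratins and breast epithelial markers (0.555), reference genes (0.586), centrosome and centriole genes (0.739), mitotic exit genes (0.856) and cholesterol and lipid synthesis genes (0.856). It also held for condensin, cohesin and topoisomerase genes, interferon response genes and small RNA machinery (0.932 each), for CDK inhibitors and p53 targets (0.932; 1 rose adjusted over the list alone) and for NF-kB and inflammatory cytokine genes (0.932; 2 rose and 3 fell adjusted over the list alone).

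In all, 12 probe sets (10 named genes) were higher and 12 (7) lower after GFP siRNA than after mock, with 565 and 762 at an unadjusted p under 0.05. With an array left out the total of 24 was 0 without mock replicate 3 and without GFP siRNA replicate 1, 9 and 4 without mock replicates 1 and 2, 8 and 2 without GFP siRNA replicates 2 and 3, and 7, 5 and 5 without FoxM1 siRNA replicates 1, 2 and 3. The named genes H1-2 and SERPINE2 passed in 7 and 5 of these 9 fits, HMOX1 in 2, BTG3 in 1 and the others in 0. In the fit of the 2 groups alone none of the named genes passed (adjusted p from 0.177 for H1-2 and SERPINE2 to 0.279 for COX11). The share of higher calls was 50% and rose to 71.4% with scaling to equal medians, 66.7% with scaling to equal mean log2 values and 60.7% without the filter. Of the 24, 4 were also called in FoxM1 siRNA against mock (GOLGB1, HMOX1, MAZ and STXBP6), all in the same direction, and 17 had the same sign there. Both comparisons use the same mock arrays, which favours such agreement. Across probe sets the log2 fold changes of the 2 siRNAs against mock correlated with r = 0.471 (0.498 simulated for unchanged groups with the same mock arrays) and a covariance of 0.0317 (0.0197 simulated). None of the 68 array control probe sets passed in any comparison, and log2 differences of 3′ and 5′ control probes for GAPDH were −0.13 ± 0.07, −0.24 ± 0.02 and −0.25 ± 0.11 in FoxM1 siRNA, GFP siRNA and mock. Those for actin were 0.04 ± 0.07, 0.04 ± 0.04 and −0.03 ± 0.08.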

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

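The 9001 probe sets too dim for the filter were tested only in the alternative without it, and there a few passed the threshold, outside the 13214 probe sets of the report's comparisons. Against GFP siRNA 6 were higher (ADGRE1, MAB21L2, LRCH3, DHRS9, EPB41L5 and a probe set with no single symbol) and 10 lower. Against mock 4 were higher (DUSP6, LRCH3, EPB41L5 and another probe set with no single symbol) and 5 lower, and for GFP siRNA against mock 8 were higher and 7 lower. Many of these calls were steps of 1 whole number with almost no spread within a group, such as means of 2 and 3 for EPB41L5 after GFP siRNA and FoxM1 siRNA (SE 0.00137 on the log2 scale). ADGRE1 and MAB21L2 had means of 3 in both mock and FoxM1 siRNA. With values rounded to whole numbers near the floor, calls of 1 step are not evidence of an effect of FoxM1 siRNA. Larger steps, such as DUSP6 with means of 2 after mock and 4.33 after FoxM1 siRNA, also lie near the floor and stay undecided.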

How the results depend on the processing

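FOXM1 kept its fall against both controls under every alternative. Of 76 named gene results, 18 stayed past the threshold in every alternative that tested their probe set. Dim genes among these, such as AKAP12, CDH5 and QTMAN, were not tested with the filter at a mean of 20. The 76 include FOXM1 for GFP siRNA against mock, which passed in 0 alternatives. The added alternatives (scaling to equal mean log2 values and a mean of at least 20) were chosen after the data had been seen. Single gene results were the same in 1303 cases, weaker in 496 and reversed in 1, and list results were the same in 218 and weaker in 34. Counts below run higher then lower for FoxM1 siRNA against GFP siRNA (A), against mock (B), GFP siRNA against mock (C) and FoxM1 siRNA against the mean of both controls (D), then for both controls in the same direction. They are given where they moved, and the cause was not tested unless stated. Median scaling gave 16 higher (A), 18 higher (B), 5 and 2 (C), 16 higher (D) and 30 against both. It shifts arrays by a rounding step of their whole-number medians, so these moves may reflect rounding, at least in part. Without the filter, where more probe sets are tested, the counts were 26 and 54 (A), 21 and 36 (B), 36 and 71 (D) and 28 against both. Quantile normalization and the filter at the 60th percentile each left 2 lists (A), and the latter gave 6 lists (C). With the replicate block the counts were 25 and 56 (A), 24 higher (B), 1 and 1 (C), 29 and 69 (D) and 32 against both. Deviations from the group means were correlated between arrays of different groups. With the same replicate number r lay from −0.079 to 0.038, and with other numbers from −0.075 to 0.117. These values show no closer match of arrays with the same number, but do not exclude a shared batch. Without the mean-variance trend they were 17 and 32 (A), 10 and 21 (B), 1 and 0 (C), 13 and 43 (D) and 19 against both. With only the 2 groups compared, which leaves fewer arrays, they were 25 and 59 (A), 4 and 16 (B), 0 and 0 (C) and 14 against both. Array weights gave 99 and 143 (A), 7 and 6 (C) and 100 and 176 (D). With 1 probe set per gene, which tests fewer, 40 were lower (B) and 7 and 4 changed (C). An adjusted p under 0.01, a stricter threshold by construction, left 10 and 30 (A), 9 and 29 (B), 0 and 0 (C), 13 and 44 (D) and 19 against both. At least 1.5-fold, also stricter, left 57 lower (A), 26 higher (B), 6 higher (C) and 23 and 52 (D). The estimated correlation left 0 lists in each comparison. Scaling to equal mean log2 values gave 6 lower (C). With 1 array left out, counts ranged from 10 to 52 and 34 to 109 (A), 9 to 28 and 32 to 64 (B), 0 to 5 and 0 to 4 (C), 9 to 54 and 34 to 106 (D) and 20 to 39 against both. In these fits lists ranged from 3 to 5, 2 to 5 and 2 to 4, and the FOXM1 log2 fold change against GFP siRNA from −2.53 to −2.39. For GFP siRNA against mock it ranged from −0.17 to 0.00049, a reversal of sign without mock replicate 1. Signal near the floor limits what dim genes can show.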

Other observations

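The tests of DR1, of the G2/M genes and of GFP siRNA against mock were chosen only after the results had been seen, and the splits of the arrays were planned before. The 42 G2/M genes below were also listed after the results had been seen, and they include genes already found to fall, such as CDKN3. With 3 arrays against 3 and the third group kept, the real grouping ranked 1 of 10 for probe sets against GFP siRNA (140, highest other 0), against mock (125, highest other 0) and for GFP siRNA against mock (24, highest other 0). For lists it ranked 1 of 10 (4, highest other 3), 1 of 10 (5, highest other 3) and 2 of 10 (3, highest other 6). Such splits are too few for a share under 0.05. Of all 84 splits of the arrays into 3 and 6, the FoxM1 siRNA arrays ranked 1 with 116 probe sets (highest other 18). Of 100 splits into 3 groups the real one ranked 1 with 50 against both controls (highest other 32). A chance split of the arrays is therefore unlikely for these counts, but not excluded. If the replicates were technical, any difference between cultures could give the same rank.

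DR1 had the largest fall after FOXM1 among genes read from their brightest probe set, and it fell less far than FOXM1 (log2 fold change −1.64 and −2.46 against GFP siRNA). Probes shared with other transcripts would leave a probe set with unique probes unchanged. The DR1 probe set whose name marks its probes as unique fell by 1.95 on the log2 scale (SE 0.17), against a median of −1.74 for the other 3. This argues against that explanation, as far as the name is right. Shared probes were not checked for the other named genes, including FOXM1 with its single probe set. Fewer cells in G2/M were predicted to lower G2/M genes as far as DR1. The median of the 42 genes lay 1.61 above DR1 against GFP siRNA (SD over genes 0.374) and 1.35 above it against mock (SD 0.389). DR1 was picked for its large fall, so the median of almost any list would lie above it. The gap therefore cannot decide whether fewer G2/M cells played a part, and this stays open. As hypotheses, a direct effect of FOXM1 loss and an off-target effect of the siRNA also remain open and were not tested. An siRNA of another sequence against FoxM1, or a rescue with FOXM1 that the siRNA does not target, would tell an off-target effect from FOXM1 loss.

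Some G2/M genes fell and others did not. The test took it that the 42 tested genes would shift together if fewer cells in G2/M were the whole cause. Their median log2 fold change was −0.0273 against GFP siRNA (SD over genes 0.374; 9 fell with a median of −0.629, and 19 lay above 0) and −0.141 against mock (SD 0.389; 9 fell with a median of −0.809, and 16 lay above 0), where the G2/M list was lower (camera adjusted p = 0.000198). The genes that fell were picked for having fallen, so their median had to lie below that of all 42. The values show that the median of the 42 genes stayed near 0 against GFP siRNA. They cannot decide on the cause, since how far each gene follows the number of G2/M cells was not measured. Fewer G2/M cells, as the whole or a part of the cause, stay open. As a hypothesis, a loss of FOXM1 activity at some of these genes also remains open, and cell cycle profiles of the same cultures would test it.

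Genes that differed between GFP siRNA and mock were tested for an effect shared by both siRNAs. The 24 probe sets with the smallest p were picked without 1 GFP siRNA array at a time, whether or not they passed. Without GFP siRNA replicates 1, 2 and 3, 0, 8 and 2 probe sets passed the threshold. The left-out array lay a median of 0.439 from the FoxM1 siRNA arrays in the direction of the difference (mean of 3, SD 0.0890). Distances from mock are not given, since the same mock arrays chose the probe sets. The distance from the FoxM1 siRNA arrays argues against a shared effect as the whole cause for the probe sets picked. A shared effect on part of these genes stays open. Of the 24, 4 were also called for FoxM1 siRNA against mock in the same direction (GOLGB1, HMOX1, MAZ and STXBP6), and 17 had the same sign. The same mock arrays serve both comparisons, so such agreement can arise without a shared effect. Across all probe sets the covariance was 0.0317 (0.0197 simulated), but the correlation was 0.471, below the 0.498 simulated. These values do not decide it. As a hypothesis, an effect of the GFP siRNA alone on the rest of the 24 remains open, and a control siRNA of another sequence would test it.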
